A study of Homo sapiens with 80 samples.

How the data were processed

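The series held 80 single-colour bead arrays of U2OS cells that expressed GRalpha, GRgamma, A477T, 30iiB or E773R. Per the labels, cells grew in 6-well plates in DMEM with 5% fetal bovine serum and were given ethanol for 4 h or the hormone, at 100 nM, for 2, 4 or 24 h. RNA was purified on columns and labelled with biotin, per the labels' protocols. The series description states 4 biological replicates per condition, and the deposited replicate list held 20 lines, of which 20 named 4 arrays of 1 group.

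The deposited signal table held an intensity for each of 25204 probes on each array, without background subtraction or scaling between arrays per the file headers. Beside each intensity, per the file headers, stood a detection p-value. The deposited series matrix held 21241 probes on a scale that ran as log2 against the signals of the same arrays (median slope 0.927), with array medians between 7.89 and 7.97. All 80 arrays correlated best with their own series matrix column (lowest correlation 0.938). The scanner software and the normalisation behind the series matrix are not given in the sources used here. Signal columns were matched to samples through the array names, and 0 columns lacked a sample. The slide was read from the array names.

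Probes were named from the platform annotation given with the series. Of the 25204 probes 19291 had 1 gene symbol, 0 had several and 5913 had none here (1950 of the series matrix), so the last were left out. Gene IDs of 19274 probes matched the gene table and 17 did not. A probe was kept when its detection p was under 0.05 on at least 4 of the 80 arrays, which kept 15392 and removed 3899. Each of 12547 genes was represented by its kept probe with the highest mean over all arrays, and 2151 genes had more than 1 kept probe. Other kept probes were compared for the target genes and the genes with the largest changes, not for members of lists.

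Intensities were background-corrected with normexp, given an offset of 16, quantile-normalised and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with data handled by the package data.table (version 1.17.8). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A single limma model with a mean for each of the 20 groups (60 residual and 5.87 prior degrees of freedom) gave 32 contrasts. These were 15 responses to dexamethasone, 12 differences between the response of a variant and that of GRalpha, 4 differences from GRalpha at 0 h, and 24 h against 4 h in GRalpha. Tests were two-sided and moderated by eBayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a contrast. A gene detected on no array of a group has only a bound there. Its fold is given as "at least", from the brighter group's mean against, on each array, the higher of the probe's own value and the lowest value among detected probes (between 5.383 and 6.848, median 5.731). The number of arrays limits the precision.

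The response score for a replicate number was the mean log2 difference between the 4 h and 0 h arrays of that number over 50 genes. These had the largest rise or fall at 4 h in GRalpha with adjusted p under 0.05 in a fit without the GRalpha arrays of that number. Scores were compared by an exact two-sided permutation test of 4 against 4, with Benjamini-Hochberg values over 8 comparisons. Shared genes between alleles were set beside the number that independent lists would share.

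Gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists and contrasts of a family, and again with a correlation estimated from the residuals. The lists covered glucocorticoid-induced genes, inflammatory mediators, negative regulators of NF-kB and MAPK signalling, clock genes, metallothioneins, S phase, mitosis, cell cycle inhibitors, bone matrix, TGF-beta and YAP targets, metabolism, ion and water transport, receptor and chaperones, transcription factors induced by steroid receptors, immediate early genes, interferon response, hypoxia, unfolded protein response, apoptosis, and markers of blood, epithelial and liver cells. Of the list calls, 25 of 84 in the responses held with the estimated correlation, 2 of 58 in the differences, 0 of 7 at 0 h and 0 of 3 between 4 and 24 h.

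The rules that chose most named genes, the lists, the main tests and most alternatives were set before the data were examined. Most named genes were 11 glucocorticoid targets including NR3C1, the 5 largest rises and falls in GRalpha at each time and between 4 and 24 h, the 3 largest in each direction for each variant at 4 h and at 0 h, and the 3 most positive and most negative differences from GRalpha at 4 h. Except among the differences, all 4 arrays of the first group had to lie on 1 side of all 4 of the other. Up to 4 called members of each described list were also named, and placeholder symbols were passed over. TXNIP, HBEGF, IRS1 and RUNX1 among the genes shared by all alleles, the 18 genes shared at 0 h, and 5 of the tests of explanations, 2 of them with slide as a block, were chosen after the values were seen.

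Alternatives were no filter on dim probes, a stricter filter, no background correction, cyclic loess, scaling to the same median, the series matrix values, the mean of a gene's probes, slide as a fixed or a random block, a replicate block, a fit to the compared groups only, and leaving out single arrays. Scores were also computed over 25 and 100 genes and, for the variants alone, against the mean of the 0 h arrays. Chosen after seeing the data were a fit without the array with the fewest detected probes, array weights, the alternatives of the genes shared by all 5 alleles, and those of the list shifts outside the GRalpha responses.

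The scripts were tested on simulated data with changes planted in the 4 h GRalpha response and the 4 h A477T difference over 12547 genes. In the GRalpha response, planted changes of log2 0.5, 1 and 2 were recovered in 4 of 66, 26 of 67 and 59 of 67 genes (6.06, 38.8 and 88.1%). In the A477T difference they were recovered in 1 of 66, 7 of 67 and 47 of 67 (1.52, 10.4 and 70.1%). A bar of 80% at log2 2 had been set first, and the A477T difference missed it. The bar was then replaced by limits on bias and on false calls, so differences of this size can be missed. The largest absolute median error was 0.05, 4 of 12320 unchanged genes were called, and 4.26% of the calls in the GRalpha response were unchanged genes. In 26 contrasts without a planted change 1 gene was called, the planted list was called with 0 others, and 4 of 4 induced score differences lay below 0. The simulated noise was independent between genes and between arrays. These rates therefore leave out slide and correlated genes, and are not error rates of the real arrays.

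Across replicates the correlation of normalised values lay between 0.893 and 0.992 over 120 pairs, and 0 pairs of arrays had identical signals. Between 48.54 and 68.77% of probes were detected on an array.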

Results

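Gene expression was measured on bead arrays in U2OS cells that expressed 1 of 5 alleles of the glucocorticoid receptor (GR). U2OS is a human osteosarcoma line with little GR of its own. GRalpha is the common receptor form. GRgamma is a splice form with an extra arginine in the DNA-binding domain, and A477T carries a change in the dimer interface of that domain. The allele 30iiB carries changes in the N-terminal activation function (AF1), and E773R carries a change in the ligand-dependent activation function (AF2). Cells received the synthetic glucocorticoid dexamethasone at 100 nM for 2, 4 or 24 h, or ethanol for 4 h (the 0 h cultures). Only the 4 h arm was therefore matched in time to its control. Each of the 20 groups of allele and time held 4 biological replicates per the labels, 80 arrays in all, and p-values measure the spread between these samples. The median signal of an array ranged from 82 to 925.75 (median of the arrays 211.2), and between 12233 and 17333 probes were detected (median 15597). The arrays lay on 10 slides of 8, with at most 1 array of a group on a slide. Counts with slide as a fixed block stand beside the counts they modify. The comparisons ask how each allele changed the hormone response relative to GRalpha. Changes are log2 differences with the SE of the limma model (n = 4 arrays a group), and adjusted p-values are two-sided and Benjamini-Hochberg adjusted over 12547 genes.

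In GRalpha cells, PDK4, a kinase that restrains pyruvate oxidation, rose 235-fold by 2 h (log2 7.87, SE 0.36, adjusted p = 1.8e-28). FAM90A1 rose 83-fold (6.37, SE 0.31). The potassium channel gene KCNA5 rose 46.4-fold (5.54, SE 0.22) and the ADP-ribosyltransferase gene TIPARP 29-fold (4.86, SE 0.38). The tubulin gene TUBA3D was detected on no 0 h array and rose at least 21.3-fold (adjusted p = 1.7e-20). The growth factor gene HBEGF fell by 2.9 (SE 0.27), the cytokine gene LIF by 2.3 (SE 0.33) and the kinase gene PIM1 by 2.27 (SE 0.29). PDE4B, a cyclic AMP phosphodiesterase gene, fell at least 5.12-fold to a level not detected on any 2 h array, with its other probe at -1.55. SCG5 fell by 2.22 (SE 0.48, adjusted p = 0.0016), a call lost without GRalpha 0 h replicate 1 (log2 -1.67, adjusted p = 0.059, range over its alternatives 4.2e-05 to 0.35). In all, 224 genes changed, 164 higher and 60 lower, and 302 changed with slide as a fixed block.

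Of 22 measured glucocorticoid-induced genes, 11 rose at 2 h in GRalpha and 11 were not called. Those that rose included LAD1 (4.06), TSC22D3 (2.73) and S100P (at least 13-fold). The count was 19 adjusted over the list alone, and camera placed the list above other genes (adjusted p = 2.8e-45, and 6.7e-36 with slide as a fixed block). Of 14 negative regulators of NF-kB and MAPK signalling, 3 rose, among them ZFP36 (1.95) and SOCS1 (1.23). Camera gave adjusted p = 1e-06 (1e-04 with slide as a fixed block). Adjusted over the list alone, 6 rose and 1 fell. Of 23 genes of glucose, lipid and amino acid metabolism 5 rose, adjusted over the list alone 5 rose and 1 fell (adjusted p = 9.9e-06, and 0.0011 with slide as a fixed block). These 3 lists also held with an estimated correlation (adjusted p = 1.2e-11, 0.009 and 0.029). Lists can share genes, such as FOXO1, so their calls are not separate evidence. Of 26 transcription factors induced by steroid receptors, 6 rose, including BCL6 (1.99) and FOXO1 (1.82), and 1 fell. Adjusted over the list alone, 10 rose and 1 fell (adjusted p = 1.9e-05, 0.0054 with slide as a fixed block, and adjusted p = 0.07 with an estimated correlation). Metallothionein genes had a median of 0.6 with 0 of 7 called by limma, 1 adjusted over the list alone (camera adjusted p = 0.0039, 0.0017 with slide as a fixed block, and adjusted p = 0.18 with an estimated correlation). The lists of cell cycle inhibitors (1 of 19 rose, adjusted over the list alone 3) and of bone matrix genes (2 of 22 rose, adjusted over the list alone 2 rose and 1 fell) were called at adjusted p = 0.037 and 0.046. Both calls were lost with slide as a fixed block (adjusted p = 0.27 and 0.11) and with an estimated correlation (adjusted p = 0.38 and 0.2). Among lists not called at 2 h, median and mean differed in sign for clock genes (0.01 and -0.01) and liver markers (-0.06 and 0.26).

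At 4 h in GRalpha, TUBA3D rose at least 128-fold (adjusted p = 3.9e-30), PDK4 rose 139-fold (log2 7.12, SE 0.36) and KCNA5 52.3-fold (5.71, SE 0.22). FAM90A1 rose 74.4-fold (6.22, SE 0.31), and the calcium channel gene CACNA1I rose 83.6-fold on the brighter of its probes (6.39, SE 0.47), whereas its other probe moved by 0.04. The neutrophil chemokine gene CXCL8 fell by 4.74 (SE 0.94, adjusted p = 0.00019), the monocyte chemokine gene CCL2 by 3.49 (SE 0.67, adjusted p = 0.00011) and LIF by 3.6 (SE 0.33, adjusted p = 6.2e-14). IRS1, which links the insulin receptor to its kinases, fell by 2.82 (SE 0.27), and PDE4B fell at least 4.85-fold. CXCL8 lost its call when only the arrays of the compared groups were fitted (adjusted p = 0.058, range over its alternatives 2.7e-07 to 0.058). In all, 606 genes changed, 356 higher and 250 lower, and 788 changed with slide as a fixed block.

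Of the glucocorticoid-induced list, 10 of 22 rose at 4 h, 16 adjusted over the list alone (camera adjusted p = 1.7e-23, 1.2e-20 with slide as a fixed block, and adjusted p = 2.5e-07 with an estimated correlation), including LAD1 (5.23), TIPARP (4.62) and S100P (at least 21.3-fold). Of 19 inflammatory mediators, 5 fell and 2 rose, the latter including PTGES (at least 6.95-fold), which makes prostaglandin E2. Adjusted over the list alone, 6 fell and 2 rose. The list test gave adjusted p = 0.045, which was lost in 5 of its 6 alternatives, among them slide as a fixed block (0.053) and the highest, adjusted p = 0.56 with an estimated correlation. Of 23 TGF-beta and YAP targets 4 fell, and adjusted over the list alone 8 fell and 3 rose (adjusted p = 0.0068, 0.012 with slide as a fixed block, and adjusted p = 0.052 with an estimated correlation). Of 15 immediate early genes 2 fell, 5 adjusted over the list alone (adjusted p = 0.0023, 0.011 with slide as a fixed block, and adjusted p = 0.48 with an estimated correlation). Of 7 metallothionein genes 2 rose, 3 adjusted over the list alone (adjusted p = 0.0077 in the model and with slide as a fixed block, and adjusted p = 0.21 with an estimated correlation). The other lists were not called at 4 h, and among them median and mean differed in sign for cell cycle inhibitors (-0.07 and 0.21) and bone matrix genes (-0.02 and 0.19).

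By 24 h in GRalpha, TUBA3D had risen at least 1040-fold (adjusted p = 1.5e-38) and PNLIP, the gene of pancreatic lipase, 516-fold (log2 9.01, SE 0.3). ART3 rose at least 189-fold, PDK4 239-fold (7.9, SE 0.36) and CACNA1I 213-fold (7.73, SE 0.47; other probe 0.11). CXCL8 fell at least 94.6-fold (adjusted p = 5e-09), TGFBI, a matrix protein gene induced by TGF-beta, at least 43.8-fold (adjusted p = 2.1e-30), and CCL2 by 5.92 (SE 0.67). The tight junction gene CLDN1 fell by 4.83 (SE 0.67) and SYTL2 by 4.83 (SE 0.31), with its other probes at -1.28 and -0.57. In all, 2239 genes changed, 1089 higher and 1150 lower, and 3129 with slide as a fixed block. No ethanol culture of 24 h was measured, so changes at 24 h, here and below, are not set apart from time in culture.

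Of the fixed lists, S phase and DNA replication had the most genes called lower at 24 h in GRalpha: 18 of 27 fell and 9 were not called, and 21 fell adjusted over the list alone. Its median of -0.84 lay nearer 0 than those of the immediate early and inflammatory lists (-1.17 and -1.04). CDC6, which loads the replicative helicase, fell by 1.47, and the helicase genes MCM6 and MCM4 by 1.37 and 1.29. Camera gave adjusted p = 1.4e-08, 6.4e-09 with slide as a fixed block, and adjusted p = 0.15 with an estimated correlation. Genes of mitosis were not called as a list (adjusted p = 0.79). Among 19 cell cycle inhibitors 5 rose and 2 fell, 6 and 2 adjusted over the list alone, with SESN1 at 2.93, FOXO1 at 2.53 and CDKN1C, the gene of p57, at 2.45, but the list was not called (adjusted p = 0.068). Of 19 inflammatory mediators 7 fell, 7 adjusted over the list alone (adjusted p = 2e-05, 0.00014 with slide as a fixed block, and adjusted p = 0.15 with an estimated correlation). Of 23 TGF-beta and YAP targets 10 fell and 2 rose, the same numbers adjusted over the list alone, including CNN1 (-3.31), TGFB2 (-2.81) and THBS1 (-2.76). That list held with slide as a fixed block (adjusted p = 0.0046) and with an estimated correlation (adjusted p = 0.031). Of 15 immediate early genes 7 fell, adjusted over the list alone 10 fell and 1 rose, including FOSL1 (-2.41) and ATF3 (-2.18). Camera gave adjusted p = 0.00069, 0.00083 with slide as a fixed block, and adjusted p = 0.42 with an estimated correlation.

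Interferon response genes rose in 3 of 17 cases at 24 h in GRalpha, 3 adjusted over the list alone, led by IFI44L (4.58) and IFIT3 (1.28). The list test gave adjusted p = 0.014 in the model and with slide as a fixed block, and adjusted p = 0.26 with an estimated correlation. Of the glucocorticoid-induced list 13 of 22 genes were higher at 24 h and 1 lower, 14 and 1 adjusted over the list alone (adjusted p = 8.1e-10, 6.4e-09 with slide as a fixed block, and adjusted p = 0.0011 with an estimated correlation). The remaining lists were not called at 24 h, although single members moved far. Among bone matrix genes DCN, the gene of the collagen-binding proteoglycan decorin, was at 3.78, the parathyroid hormone receptor gene PTH1R at 3.68 and TNFRSF11B, the gene of the osteoclast inhibitor osteoprotegerin, at -3.14 (list adjusted p = 0.76). KLF15 (3.87), CPT1A (2.71), KCNMA1 (2.7), MT1X (3.02) and TF (at least 9.92-fold) rose, while HES1 (-2.86), BHLHE41 (-1.8) and HSP90AA1 (-0.98) fell. Their lists of transcription factors, metabolism, ion transport, liver markers, metallothioneins, clock genes and receptor chaperones had adjusted p = 0.13, 0.093, 0.63, 0.16, 0.056, 0.97 and 0.23. Hypoxia, unfolded protein response, apoptosis, blood and epithelial marker lists had adjusted p = 0.95, 0.17, 0.85, 0.9 and 0.66, and the negative regulators of NF-kB and MAPK signalling 0.36. Median and mean differed in sign for clock genes (0.32 and -0.03), apoptosis genes (0.04 and -0.1) and blood markers (0.07 and -0.15), and the hypoxia list had a median of 0.04 with a test direction of down.

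Between 4 and 24 h in GRalpha, compared without the shared 0 h arrays, 1384 genes changed, 683 higher and 701 lower, and 1750 changed with slide as a fixed block. TEDDM1 rose 26.9-fold (log2 4.75, SE 0.41), PNLIP 24.7-fold (4.63, SE 0.3), and IFI44L 17.8-fold (4.15, SE 0.26). The hormone gene STC1 rose 17.5-fold (4.13, SE 0.3) and FAM117A 16-fold (4, SE 0.3). TGFBI fell at least 17.2-fold and the crystallin gene CRYGC at least 9.97-fold. KCNJ4 fell by 3.83 (SE 0.38), CFAP58 by 3.81 (SE 0.56) and SYTL2 by 3.77 (SE 0.31). Of the S phase list 13 of 27 fell, 17 adjusted over the list alone (adjusted p = 2.3e-09, 2.9e-09 with slide as a fixed block, and adjusted p = 0.31 with an estimated correlation). Of the inflammatory list 5 of 19 fell, 6 adjusted over the list alone (adjusted p = 0.00022, 0.00099 with slide as a fixed block, and adjusted p = 0.37 with an estimated correlation). Interferon genes had a median of 0.17 with 2 of 17 higher, 3 adjusted over the list alone (adjusted p = 0.044, 0.082 with slide as a fixed block, and adjusted p = 0.37 with an estimated correlation).

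**Figure D1:**
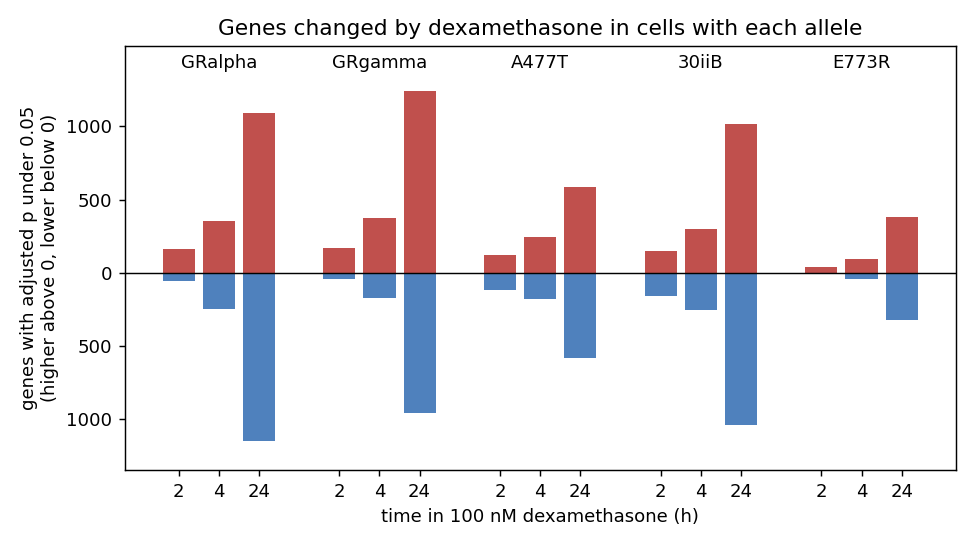
Number of genes with adjusted p under 0.05 at 2, 4 and 24 h of dexamethasone against the 0 h cultures of the same allele, with higher genes drawn above 0 and lower genes below. The counts rose from 224 at 2 h to 2239 at 24 h in GRalpha and from 45 to 702 in E773R.

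Among the glucocorticoid target genes set in advance, TSC22D3 rose at 2, 4 and 24 h in GRalpha (log2 2.73, 2.66 and 3.23, SE 0.35), with its other probes moving alike, and ZBTB16, a zinc finger repressor gene, rose by 1.96, 3.55 and 4.37 (SE 0.39). The other ZBTB16 probes moved less, by 0.3, 0.9 and 1.33 and by 1.21, 2.44 and 3.01. SGK1, a kinase gene of sodium transport, rose by 1.74, 1.33 and 1.15 (SE 0.32). With only the compared groups in the fit the 2 h calls of ZBTB16 and SGK1 were lost (adjusted p = 0.11 and 0.28, ranges over the alternatives 9.2e-07 to 0.11 and 1.8e-06 to 0.28). Without GRalpha 0 h replicate 3 the SGK1 calls at 4 and 24 h were lost (log2 0.93 and 0.75, adjusted p = 0.089 and 0.11, ranges over the alternatives 6.7e-05 to 0.14 and 0.00014 to 0.11). KLF9 rose by 1.28 at 2 h and 1.42 at 24 h (SE 0.3), but the 2 h call was lost with slide as a fixed block (0.93, adjusted p = 0.056, range 0.00062 to 0.39), and without GRalpha 0 h replicate 3 or 2 h replicate 1 (1.07 each). DUSP1, a MAPK phosphatase gene, rose by 0.9 at 24 h (SE 0.26, adjusted p = 0.0092), a call lost without GRalpha 0 h replicate 3 (0.63, adjusted p = 0.11, range 0.00012 to 0.14). At 2 and 4 h DUSP1 was at 0.85 and 0.57 without a call, and without GRalpha 0 h replicate 2 it was at 1.22 and 0.94 and called. PER1, ANGPTL4 and GLUL were not called at any of these times in GRalpha, and FKBP5 and IGFBP1 were not measured.

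The probe of NR3C1, the GR gene itself, fell by 1.35, 1.71 and 1.14 (SE 0.34) at 2, 4 and 24 h in GRalpha, and its other probe moved by -0.73, -0.38 and -0.47. Where these probes lie relative to the expressed construct is not given in the sources used here, so they do not separate construct from endogenous transcript and do not check the alleles. The 2 h call was lost without any of GRalpha 0 h replicates 1 and 4 or 2 h replicates 2 and 3 (log2 -1.21, -1.23, -1.15 and -1.27), and the 24 h call without 0 h replicate 4 (-1.02, adjusted p = 0.052, range 0.00015 to 0.052). NR3C1 at 4 h was at -1.15 in GRgamma, -1.86 in A477T, -1.44 in 30iiB and -1.11 in E773R, of which the last was not called (adjusted p = 0.1). At 0 h NR3C1 did not differ from GRalpha by the test in any variant (GRgamma -0.96, A477T -0.23, 30iiB -0.46, E773R -0.33; adjusted p = 0.38, 0.81, 0.66 and 1). The GRgamma value was -0.4 without GRgamma 0 h replicate 1, the array of that group on which NR3C1 was not detected (adjusted p = 1, range over its alternatives 0.14 to 1).

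A set of 55 genes moved the same way in all 5 alleles at 4 h, 40 higher (3.6e-05 would by chance, were the lists independent) and 15 lower (3.8e-06). Without E773R 4 h replicate 2 the 15 became 7, with fits to the compared groups alone the numbers were 15 and 0 by limma, and with arrays scaled to the same median 19 and 4. PDK4 rose by 7.12 in GRalpha, 5.74 in GRgamma, 4.22 in A477T, 6.84 in 30iiB and 6.4 in E773R, and TXNIP, an inhibitor of thioredoxin, by 4.36, 4.48, 1.66, 3.64 and 2.25. Among those that fell were HBEGF (-2.77, -3.06, -1.87, -3.29 and -1.34), IRS1 (-2.82, -2.73, -2.2, -3.2 and -1.03) and RUNX1 (-1.76, -1.3, -1.65, -1.61 and -1.43), a transcription factor gene of the bone and blood lineages. These 3 and TXNIP were chosen after their values were seen. At 2 h 17 genes rose and 1 fell in all 5, and at 24 h 144 rose and 161 fell. Of the genes that rose in each variant at 4 h, 199 of 372 in GRgamma, 110 of 243 in A477T, 211 of 299 in 30iiB and 80 of 92 in E773R also rose in GRalpha (independent lists would share 10.6, 6.89, 8.48 and 2.61). Of those that fell, 126 of 176, 102 of 180, 143 of 257 and 33 of 46 also fell in GRalpha (3.51, 3.59, 5.12 and 0.917).

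**Figure D2:**
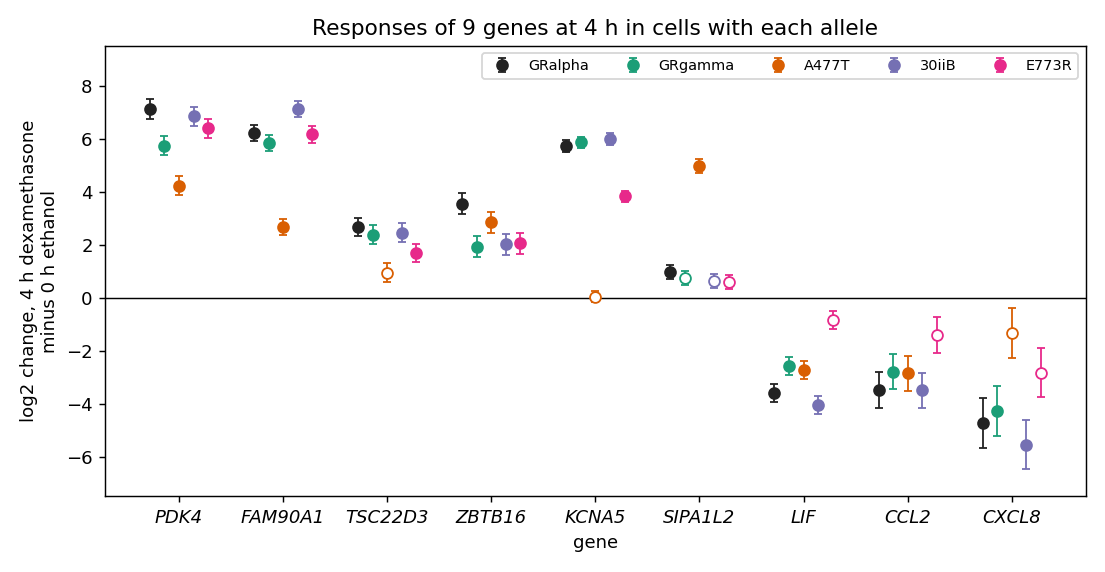
Log2 change from 0 to 4 h with its SE (n = 4 arrays a group) for 9 genes in cells with each allele, where filled points passed the test and open points did not. Points of genes not detected in a group depend on the background level. PDK4 and FAM90A1 rose in all 5 alleles, KCNA5 was detected on no A477T array at 0 or 4 h, SIPA1L2 rose by 4.96 in A477T, and LIF was at -0.85 without a call in E773R.

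A response score gave the 4 h change over 50 genes induced and 50 repressed in GRalpha, chosen for each replicate number without the GRalpha arrays of that number. The induced score was 3.86 ± 0.11 (SD, n = 4) in GRalpha, 3.14 ± 0.07 in 30iiB, 2.63 ± 0.11 in GRgamma, 2.02 ± 0.12 in E773R and 1.71 ± 0.31 in A477T, that is 81.3, 68.1, 52.3 and 44.3% of GRalpha in that order. Each variant differed from GRalpha in the two-sided exact permutation test (p = 0.0286, the smallest that 4 against 4 allow, and 0.0457 after Benjamini-Hochberg adjustment over the 8 comparisons). All 4 scores of each variant lay below all 4 of GRalpha. As each allele was read in its own cells, the test does not set any of the alleles apart from the cell population that carries it. As the genes were those that changed most in GRalpha, an equally strong response of other genes would also score lower, and the percentages hold for these genes alone. The repressed score was 1.97 ± 0.21 in GRalpha and fell short of it in E773R alone by this test (1.09 ± 0.21, 55.3% of GRalpha, exact p = 0.0286, adjusted 0.0457). It was 1.85 ± 0.11 in GRgamma (exact p = 0.343), 1.54 ± 0.19 in A477T (exact p = 0.0571, adjusted 0.0762) and 2.28 ± 0.20 in 30iiB (exact p = 0.0857, adjusted 0.098). With each 4 h array of a variant set against the mean of its 0 h arrays, the A477T difference of -0.47 passed the test. GRalpha kept its same-numbered 0 h arrays there, so the 2 sides of that comparison had unlike baselines. Pairs of 4 and 0 h arrays on a shared slide gave induced scores of 3.99 in GRalpha, 2.4 and 2.69 in GRgamma, 2.09 and 1.77 in A477T, 3.1 in 30iiB, and 1.74 and 2.09 in E773R. Their repressed scores were 2.17, 1.96 and 1.72, 1.5 and 1.41, 2.14, and 0.71 and 1.01.

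**Figure D3:**
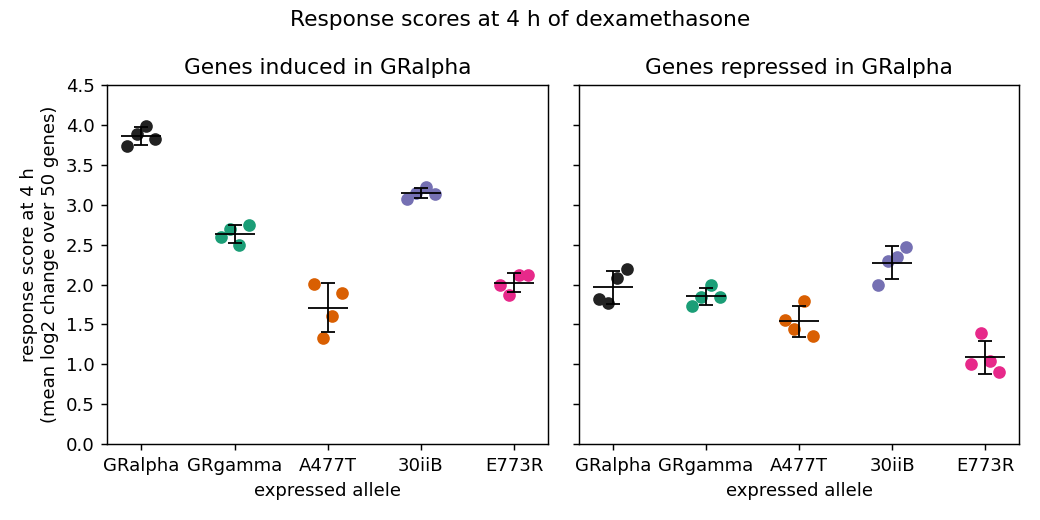
Response scores at 4 h, the mean log2 change over 50 genes with the sign turned for repressed genes, with a point for each replicate number and bars for the mean and SD (n = 4). The induced scores of E773R reached 2.12 at most and those of GRalpha were 3.73 or more.

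GRgamma changed 210 genes at 2 h (166 higher, 44 lower), 548 at 4 h (372 and 176) and 2207 at 24 h (1245 and 962), or 318, 746 and 2708 with slide as a fixed block. At 4 h KCNA5 rose at least 35.4-fold, FAM90A1 57.2-fold (log2 5.84, SE 0.31) and PDK4 53.4-fold (5.74, SE 0.36). CXCL8 fell by 4.27 (SE 0.94), RGS4, a regulator of G protein signalling, by 3.38 (SE 0.35) and HBEGF by 3.06 (SE 0.27). Of the glucocorticoid-induced list 11 of 22 rose, 14 adjusted over the list alone (adjusted p = 1.4e-15, 1.6e-13 with slide as a fixed block, and adjusted p = 2e-05 with an estimated correlation). TSC22D3 rose by 2.38 and ZBTB16 at least 2.56-fold. Scaling every array to the same median gave 122 higher and 9 lower genes at 2 h and 988 and 468 at 24 h.

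The response differed from that of GRalpha in 14 genes at 2 h (6 with a more positive change in GRgamma, 8 with a more negative one), 45 at 4 h (18 and 27) and 244 at 24 h (134 and 110), or 18, 51 and 340 with slide as a fixed block. At 4 h the difference was 3.73 (SE 0.38) for SYT13, a synaptotagmin gene, 2.94 (SE 0.52) for ARHGEF16 and 2.45 (SE 0.52, adjusted p = 0.0069) for PLEKHF1. It was -3.59 (SE 0.39) for TMIGD3, -3.43 (SE 0.32) for CTCFL and -3.27 (SE 0.42) for the transferrin gene TF, which rose at least 12-fold, 5.77-fold and 8.19-fold in GRalpha. SYT13, TMIGD3 and TF were not detected in 2 of the 4 groups and CTCFL in 3, so the sizes of their differences depend on the background level. Of the 45 genes, 19 had been called in GRalpha alone, 15 in GRgamma alone and 11 in both. The glucocorticoid-induced list had a median difference of -0.35 at 4 h with 0 of 22 genes called by limma and 2 lower adjusted over the list alone (camera adjusted p = 0.00038, 4.1e-05 with slide as a fixed block, and adjusted p = 0.14 with an estimated correlation). PLEKHF1 lost its call without GRalpha 4 h replicate 1 (2.12, adjusted p = 0.058, range over its alternatives 3e-04 to 0.11), and the 2 h count was 9 without GRgamma 0 h replicate 2, GRgamma 2 h replicate 2 or GRalpha 2 h replicate 2. Scaling to the same median gave 3 and 8 genes at 2 h, 8 and 21 at 4 h, and 93 and 124 at 24 h.

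A477T changed 235 genes at 2 h (120 higher, 115 lower), 423 at 4 h (243 and 180) and 1166 at 24 h (584 and 582), or 282, 594 and 1440 with slide as a fixed block. At 4 h the proton pump gene ATP4A rose 31.7-fold (log2 4.99, SE 0.35), SIPA1L2 31.1-fold (4.96, SE 0.26) and KDF1 at least 17.4-fold. BDNF, a neurotrophin gene, fell by 3.26 (SE 0.38, with a smaller change as the mean of its probes), CCL2 by 2.86 (SE 0.67) and LIF by 2.73 (SE 0.33). Of the glucocorticoid-induced list 7 of 22 rose and 1 fell, 9 and 1 adjusted over the list alone (adjusted p = 4.1e-06, 1.6e-05 with slide as a fixed block, and adjusted p = 0.023 with an estimated correlation). ZBTB16 rose at least 4.46-fold and SGK1 by 1.14, TSC22D3 was at 0.94 without a call (adjusted p = 0.17), and DUSP1 fell by 0.94 (adjusted p = 0.023).

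A477T and GRalpha responses differed in 57 genes at 2 h (22 more positive in A477T, 35 more negative), 177 at 4 h (70 and 107) and 635 at 24 h (323 and 312), or 65, 200 and 895 with slide as a fixed block. Among the 177 genes, 90 had been called in GRalpha alone, 54 in A477T alone, 29 in both and 4 in neither. The difference at 4 h was 4.89 (SE 0.47) for the sulfotransferase gene CHST15, 4.7 (SE 0.5) for ATP4A and 4 (SE 0.37) for SIPA1L2, of which CHST15 fell by 1.28 in GRalpha, ATP4A was not called and SIPA1L2 rose at least 1.59-fold. It was -5.67 (SE 0.32) for KCNA5, -5.36 (SE 0.85) for the calcium-binding protein gene S100P and -4.64 (SE 0.49) for ART3, which rose 52.3-fold, at least 21.3-fold and at least 19.5-fold in GRalpha. KCNA5 was not detected in 2 of the 4 groups, ART3 in 3 and the other 4 genes in 1, so these sizes depend on the background level. DUSP1 differed by -1.7 at 2 h (SE 0.37, adjusted p = 0.007) and -1.52 at 4 h (SE 0.37, adjusted p = 0.012), and TSC22D3 by -2.64 at 24 h (SE 0.49, adjusted p = 7.2e-05). The glucocorticoid-induced list had a median difference of -0.8 at 2 h and -0.92 at 4 h, with 4 of 22 genes lower at each time and 8 and 7 adjusted over the list alone. Camera gave adjusted p = 3.5e-11 and 5.2e-09, 2.9e-18 and 2.5e-10 with slide as a fixed block, and adjusted p = 0.0018 and 0.0059 with an estimated correlation. Scaling to the same median gave 12 more positive and 34 more negative genes at 2 h.

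30iiB changed 306 genes at 2 h (148 higher, 158 lower), 556 at 4 h (299 and 257) and 2056 at 24 h (1015 and 1041), or 316, 635 and 2626 with slide as a fixed block. At 4 h FAM90A1 rose at least 102-fold, PDK4 115-fold (log2 6.84, SE 0.36) and KCNA5 63.7-fold (5.99, SE 0.22). CXCL8 fell by 5.55 (SE 0.94), LIF by 4.06 (SE 0.33) and RGS4 by 3.71 (SE 0.35). Of 22 glucocorticoid-induced genes 9 rose, 12 adjusted over the list alone (adjusted p = 2.4e-14, 4.6e-16 with slide as a fixed block, and adjusted p = 4.4e-05 with an estimated correlation). Of 19 inflammatory mediators 7 fell and 2 rose, 10 and 2 adjusted over the list alone (adjusted p = 2.1e-08, 3.8e-07 with slide as a fixed block, and adjusted p = 0.045 with an estimated correlation). TSC22D3 rose by 2.45 and ZBTB16 by 2.01.

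In the test of the difference from GRalpha, 30iiB differed in 0 genes at 2 h, 6 at 4 h (2 more positive, 4 more negative) and 48 at 24 h (20 and 28), or 0, 5 and 69 with slide as a fixed block. At 2 h 271 genes had an unadjusted p under 0.05 in limma, where 627 would by chance, and 1 gene was called without 30iiB 0 h replicate 3 or 4 or 30iiB 2 h replicate 4. At 2 h 8 lists were nonetheless called lower than in GRalpha, with 0 members called by limma and none held with an estimated correlation. With slide as a fixed block 4 of them held: immediate early genes (median -0.49, adjusted p = 8.9e-05, slide 0.00033, estimated 0.36), metabolism (-0.39, adjusted p = 0.00014, slide 0.02, estimated 0.12), glucocorticoid-induced genes (-0.34, adjusted p = 0.00056, slide 0.027, estimated 0.15) and metallothioneins (-0.5, adjusted p = 0.025, slide 0.042, estimated 0.36). The last list was higher than in GRalpha before hormone (0 h median 0.77), a level that the difference of responses contains. At 4 h ARHGAP39, which rose at least 5.01-fold in GRalpha and was not detected in 30iiB at 0 or 4 h, differed by -3.03 (SE 0.39, adjusted p = 6.1e-07), GPR65 by -1.78 (SE 0.32) and the cartilage matrix gene CILP by 1.55 (SE 0.27). ARHGAP39, GPR65 and CILP were each not detected in 3 of the 4 groups and TUBA3D in 1, so these sizes depend on the background level. GPR65 was not detected in GRalpha at 0 or 4 h and was at least 2.36-fold higher in 30iiB at 0 h (adjusted p = 1.4e-07). GPR65 and CILP lost their calls with arrays scaled to the same median (-1.96 and 1.34, adjusted p = 0.54 and 0.86) and with only the compared groups in the fit. Over their alternatives they ranged from -2.08 to -0.65 (adjusted p 3.3e-05 to 0.58) and from 0.69 to 1.73 (7.5e-05 to 0.86). TUBA3D differed by -2.12 (SE 0.46) and ASPHD2 by 1.12 (SE 0.24), both at adjusted p = 0.046. These calls were lost with slide as a fixed block (log2 -1.89 and 1.08, adjusted p = 0.13 and 0.098), with sizes near those without it, and in 13 and 14 of the fits that left out a single array (ranges over the alternatives 0.0092 to 0.18 and 0.0042 to 0.86). The 4 h count was 10 without GRalpha 0 h replicate 1. It was 3 without 30iiB 0 h replicates 2, 3 or 4, 30iiB 4 h replicate 4, GRalpha 0 h replicate 4, or GRalpha 4 h replicates 1 or 3. The 24 h count was 31 without 30iiB 0 h replicate 2 and 30 without GRalpha 0 h replicate 4. Other scalings gave 2 more positive and 10 more negative genes (cyclic loess) or 0 and 3 (same median) at 4 h, and 4 and 9 (same median) at 24 h.

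E773R changed 45 genes at 2 h (42 higher, 3 lower), 138 at 4 h (92 and 46) and 702 at 24 h (379 and 323), or 59, 153 and 1118 with slide as a fixed block. At 4 h PDK4 rose 84.3-fold (log2 6.4, SE 0.36), FAM90A1 71.4-fold (6.16, SE 0.31) and TUBA3D at least 30.4-fold. The phosphatase gene PTPRE fell by 2.37 (SE 0.51), NAV3 by 2.09 (SE 0.38) and PDE4B by 2.03 (SE 0.35). NAV3 and PDE4B lost their calls with only the compared groups fitted (adjusted p = 0.28 and 0.1). PTPRE probes disagreed in GRalpha at 4 h (-2.11 on the one used, -0.15 and -1.21 on the others). Of the glucocorticoid-induced list 7 of 22 rose, 11 adjusted over the list alone (adjusted p = 1.4e-15, 1e-18 with slide as a fixed block, and adjusted p = 2e-05 with an estimated correlation). TSC22D3 rose by 1.68 and ZBTB16 at least 2.4-fold. At 2 h the 14 negative regulators of NF-kB and MAPK signalling had a median of 0.9, with 3 higher and 7 adjusted over the list alone (adjusted p = 3.3e-19, 1e-18 with slide as a fixed block, and adjusted p = 1e-06 with an estimated correlation). E773R 4 h replicate 2 had the fewest detected probes of all arrays (12233). Without it 83 genes were called at 4 h and PTPRE was not (-1.67, adjusted p = 0.16, range over its alternatives 1e-06 to 0.46), and without E773R 0 h replicate 3 89 were called. Scaling to the same median gave 37 higher and 7 lower genes at 4 h.

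For E773R the difference from GRalpha covered 16 genes at 2 h (2 more positive, 14 more negative), 61 at 4 h (9 and 52) and 216 at 24 h (86 and 130), or 23, 84 and 340 with slide as a fixed block. Of the 61 genes, 52 rose and 8 fell in GRalpha, each less or not at all in E773R. The difference was 2.75 (SE 0.46) for LIF, 2.5 (SE 0.58, adjusted p = 0.015) for the hyaluronan synthase gene HAS2 and 2.29 (SE 0.51, adjusted p = 0.0092) for IRF2BP2, and in GRalpha LIF fell by 3.6, HAS2 at least 4.41-fold and IRF2BP2 by 2. It was -4.06 (SE 0.85) for S100P, -3.94 (SE 0.39) for TMIGD3 and -3.65 (SE 0.66) for CACNA1I, which rose at least 21.3-fold, at least 12-fold and 83.6-fold in GRalpha. S100P and TMIGD3 were not detected in 2 of the 4 groups and HAS2 and CACNA1I in 1, so these sizes depend on the background level. Without E773R 4 h replicate 2 HAS2 and IRF2BP2 lost their calls (2.24 and 1.95, adjusted p = 0.069 and 0.066, ranges over the alternatives 0.00085 to 0.19 and 0.0014 to 0.066). HAS2 also lost it without E773R 0 h replicate 2 (2.12) or GRalpha 0 h replicate 4 (2.26) and as the mean of its probes (1.03), the other of which was at 0.39 in GRalpha at 4 h. S100P and CACNA1I lost their calls with only the compared groups in the fit (adjusted p = 0.065 and 0.061). The glucocorticoid-induced list had a median difference of -0.42 at 4 h with 3 of 22 genes lower, 7 lower and 1 higher adjusted over the list alone (adjusted p = 3.7e-05, 0.00042 with slide as a fixed block, and 0.12 with an estimated correlation). The 2 h count was 26 without GRalpha 2 h replicate 4.

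At 24 h the S phase list fell in 20 of 27 genes in GRgamma (24 adjusted over the list alone; adjusted p = 3.8e-17, 9.2e-17 with slide as a fixed block, and adjusted p = 0.019 with an estimated correlation). It fell in 13 in 30iiB (14 adjusted over the list alone; adjusted p = 2.7e-05, 1.6e-06 with slide as a fixed block, and adjusted p = 0.34 with an estimated correlation). In E773R and A477T 0 genes of the list were called by limma, over all genes or adjusted over the list alone. The list test gave adjusted p = 0.04 in E773R (0.0067 with slide as a fixed block, and adjusted p = 0.7 with an estimated correlation) and 0.58 in A477T. The median difference from GRalpha was 0.86 in A477T (2 genes higher, 12 adjusted over the list alone; adjusted p = 9.6e-08, 5e-09 with slide as a fixed block) and 0.65 in E773R (1 higher, 5 adjusted over the list alone; adjusted p = 1e-08, 1e-07 with slide as a fixed block). In GRgamma it was -0.36 (adjusted p = 0.0026, 0.0049 with slide as a fixed block) and in 30iiB 0.21 (adjusted p = 0.013, 0.084 with slide as a fixed block), with 0 genes called in either. None of these 4 differences held with an estimated correlation (adjusted p = 0.25, 0.21, 0.58 and 0.65). Inflammatory mediators were called lower at 24 h in the variants too. In A477T 8 of 19 fell and 1 rose, 11 and 1 adjusted over the list alone (adjusted p = 3.8e-08, 1.2e-08 with slide as a fixed block, and adjusted p = 0.048 with an estimated correlation), and in E773R 8 fell, 9 adjusted over the list alone (adjusted p = 1.7e-09, 1.5e-07 with slide as a fixed block, and adjusted p = 0.028 with an estimated correlation). In GRgamma 6 fell and in 30iiB 9, 6 and 10 adjusted over the list alone (adjusted p = 0.00013 and 9.2e-07, 0.00021 and 1.6e-05 with slide as a fixed block, and adjusted p = 0.21 and 0.08 with an estimated correlation). The 24 h difference of that list from GRalpha was not called in any variant.

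Before hormone, the cancer-testis antigen gene MAGEA10 was not detected in GRalpha cells and was at least 38.4-fold higher in GRgamma, 14.7-fold in A477T, 20.1-fold in 30iiB and 14.1-fold in E773R, with its other probe at 0.72 in A477T. The histone gene H4C3 was 101-fold higher in GRgamma (log2 6.66, SE 0.71) and 22.9-fold in E773R (4.52, SE 0.71), uncertain because near-identical histone genes can share a probe. C1QTNF1 was lower at least 3.74-fold in GRgamma, 4.28-fold in 30iiB and 3.9-fold in E773R, with log2 differences of -0.89, -0.9 and -1.07 as the mean of its probes. In GRgamma MAGEB1 was at least 13.8-fold higher, SHISA2 5.42-fold lower and F13A1, a coagulation factor gene, at least 3.29-fold lower. In A477T TRIML2 was 20.6-fold and SP140 16.5-fold higher, and FOXS1 was 17.4-fold, the collagen gene COL3A1 12.1-fold and LRRC32 9.28-fold lower. In 30iiB the acute phase gene SAA1 was 29-fold (4.86, SE 0.56; 2.7 as the mean of its probes) and the embryonic globin gene HBE1 11.1-fold higher, and COL3A1 was 10.7-fold and FOXS1 9.17-fold lower. In E773R LHX2 was 8.29-fold higher, CTAG2 at least 3.17-fold lower (-1.24 as the mean of its probes) and KCNIP1 4.52-fold lower.

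In all, 61 genes differed from GRalpha at 0 h in GRgamma (17 higher, 44 lower), 303 in A477T (167 and 136), 198 in 30iiB (128 and 70) and 74 in E773R (29 and 45), or 100, 326, 294 and 154 with slide as a fixed block. Among marker lists of other cell types, blood markers were higher in 30iiB, with 2 of 12 called, HBG1 (1.33) and HBG2 (at least 2.77-fold), and 3 adjusted over the list alone (adjusted p = 0.024, 0.082 with slide as a fixed block, and adjusted p = 0.12 with an estimated correlation). Epithelial and liver markers were not called at 0 h. The interferon list had a median of 0.62 in A477T with 1 of 17 genes called, 4 adjusted over the list alone, and of 0.59 in 30iiB with 1 called, 1 adjusted over the list alone (adjusted p = 0.0097 and 0.0041, and adjusted p = 0.44 and 0.36 with an estimated correlation). Inflammatory mediators had a median of 0.72 in A477T with 1 of 19 called, 2 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.68 with an estimated correlation). Metallothioneins had a median of 0.77 in 30iiB with 0 of 7 called by limma, 3 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.46 with an estimated correlation). Mitosis genes in GRgamma (0.17) and immediate early genes in E773R (-0.37) had 0 members called by limma, over all genes or adjusted over the list alone (adjusted p = 0.028 each, and adjusted p = 0.89 and 0.8 with an estimated correlation). With slide as a fixed block these 6 lists had adjusted p = 0.0041, 0.028, 0.0092, 0.031, 0.18 and 0.031. None of the 7 list calls at 0 h held with an estimated correlation. Without GRalpha 0 h replicate 4 the counts were 191 in A477T and 125 in 30iiB, without GRgamma 0 h replicate 1 36 in GRgamma, and without E773R 0 h replicate 3 42 in E773R. SP140 was lost in A477T without GRalpha 0 h replicate 3 or 4 (log2 3.57 and 3.48, adjusted p = 0.067 and 0.088, range over its alternatives 8e-05 to 0.088). Scaling to the same median gave 128 higher and 35 lower genes in 30iiB.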

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

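The tests of 2 patterns against slide, the test of the A477T response at 24 h, the fit without an E773R array and the test of a slower E773R response were chosen only after the results were seen. Results are listed here because a test of the difference between groups passed, or because 1 array lay far from the 3 others of its group.

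Responses differed from that of GRalpha in 14, 45 and 244 genes at 2, 4 and 24 h in GRgamma, 57, 177 and 635 in A477T, 6 and 48 at 4 and 24 h in 30iiB, and 16, 61 and 216 in E773R. Each count was set against 100 splits of the same arrays, the real one included. Chance was excluded for A477T at 4 h (1 of 100 splits called as many, highest other 69) and 24 h (2, highest other 1511), and for E773R at 4 h (3, highest other 103) and 24 h (3, highest other 281). The share was not under 0.05 for GRgamma at 2, 4 and 24 h (15, 6 and 5 of 100, highest others 1155, 280 and 576), A477T at 2 h (9, highest other 1814), 30iiB at 4 and 24 h (12 and 5, highest others 267 and 150) or E773R at 2 h (8, highest other 563). For 30iiB at 2 h, with 0 genes called, all 100 splits reach that count by construction (highest other 1134), so the splits decide nothing there. Splits that called several times the real count point to a structure of the samples. The splits were drawn and fitted without regard to slide, so they do not separate chance from slide. With slide as a fixed block the real counts above 0 whose share was not under 0.05 were 18, 51 and 340 in GRgamma, 65 in A477T at 2 h, 5 and 69 in 30iiB at 4 and 24 h, and 23 in E773R at 2 h.

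In the 15 responses, 35 splits each, the real split alone reached its count except in GRalpha at 2 h, where 4 splits called at least the 224 real genes and the highest other called 2700, which points to a structure of the samples. The real counts were 606 and 2239 in GRalpha at 4 and 24 h (1 of 35 each, highest others 66 and 441), 210, 548 and 2207 in GRgamma (27, 129 and 283), 235, 423 and 1166 in A477T (20, 91 and 252), 306, 556 and 2056 in 30iiB (70, 138 and 638), and 45, 138 and 702 in E773R (2, 29 and 98). At 0 h the real counts of 61, 303, 198 and 74 in GRgamma, A477T, 30iiB and E773R stood against highest others of 14, 74, 54 and 3, and between 4 and 24 h in GRalpha 1384 genes stood against 64, each reached by 1 of 35 splits. Apart from GRalpha at 2 h, each share was the smallest that 35 splits allow and was not adjusted over the contrasts. This argues against chance alone for these counts.

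Induced scores at 4 h differed from GRalpha by -1.23 in GRgamma, -2.15 in A477T, -0.71 in 30iiB and -1.84 in E773R, and the repressed score by -0.88 in E773R. The genes whose 4 h responses differed were SYT13 (3.73), ARHGEF16 (2.94), PLEKHF1 (2.45), TMIGD3 (-3.59), CTCFL (-3.43) and TF (-3.27) in GRgamma, and CHST15 (4.89), ATP4A (4.7), SIPA1L2 (4), KCNA5 (-5.67), S100P (-5.36) and ART3 (-4.64) in A477T. Where a gene was not detected in a group, the size depends on the background level. DUSP1 differed in A477T by -1.7 at 2 h and -1.52 at 4 h, and TSC22D3 by -2.64 at 24 h. In 30iiB they were CILP (1.55), ASPHD2 (1.12), ARHGAP39 (-3.03), TUBA3D (-2.12) and GPR65 (-1.78), and in E773R LIF (2.75), HAS2 (2.5), IRF2BP2 (2.29), S100P (-4.06), TMIGD3 (-3.94) and CACNA1I (-3.65). Between 4 and 24 h in GRalpha they were TEDDM1 (4.75), PNLIP (4.63), IFI44L (4.15), STC1 (4.13), FAM117A (4), TGFBI (-4.51), CRYGC (-4.16), KCNJ4 (-3.83), CFAP58 (-3.81) and SYTL2 (-3.77).

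Of 264 list tests of differences from GRalpha 58 passed. In GRgamma at 2 h the medians were -0.37 for glucocorticoid-induced genes, -0.59 for metallothioneins, 0.24 for TGF-beta and YAP targets and -0.29 for metabolism. At 4 h they were -0.35 for glucocorticoid-induced genes and -0.3 for liver markers (1 lower), and at 24 h -0.36 for S phase, -0.52 for mitosis and -0.21 for interferon genes (2 lower). In A477T at 2 h they were -0.8 for glucocorticoid-induced genes, -0.75 for metallothioneins, -0.43 for cell cycle inhibitors, -0.31 for metabolism, -0.53 for transcription factors, -0.48 for immediate early genes and -0.49 for the unfolded protein response. At 4 h they were -0.92 for glucocorticoid-induced genes, -0.73 for metallothioneins, -0.47 for cell cycle inhibitors, -0.06 for metabolism (mean -0.44, 4 lower) and -0.71 for transcription factors (3 lower). At 24 h they were -0.81 for glucocorticoid-induced genes, -0.57 for negative regulators of NF-kB and MAPK signalling, 0.86 for S phase, 0.4 for mitosis, -0.43 for cell cycle inhibitors, -0.24 for metabolism, -0.46 for transcription factors and -0.65 for interferon genes. In 30iiB 0 members of any such list were called by limma. At 2 h the medians were -0.34 for glucocorticoid-induced genes, -0.47 for inflammatory mediators, -0.5 for metallothioneins, -0.42 for cell cycle inhibitors, -0.28 for bone matrix, -0.39 for metabolism, -0.39 for transcription factors and -0.49 for immediate early genes. At 4 h they were -0.39 for glucocorticoid-induced genes, -0.55 for inflammatory mediators, -0.56 for metallothioneins, 0.29 for S phase, 0.48 for mitosis, -0.35 for transcription factors, -0.43 for immediate early genes and -0.58 for interferon genes, and at 24 h -0.64 for metallothioneins, 0.21 for S phase and -0.69 for interferon genes. In E773R at 2 h they were -0.1 for glucocorticoid-induced genes (mean -0.48), 0.77 for inflammatory mediators (2 lower), 0.38 for TGF-beta and YAP targets and 0.8 for immediate early genes. At 4 h they were -0.42 for glucocorticoid-induced genes and 0.67 for immediate early genes, and at 24 h 0.65 for S phase, 0.37 for TGF-beta and YAP targets, 0.79 for immediate early genes and -0.47 for interferon genes. A difference of responses contains the 0 h levels. These differed from GRalpha for interferon genes in A477T (0.62) and 30iiB (0.59), metallothioneins in 30iiB (0.77), mitosis in GRgamma (0.17) and immediate early genes in E773R (-0.37), so for these lists a changed response was not set apart from the level before hormone. Between 4 and 24 h in GRalpha inflammatory mediators (-0.66), S phase (-0.73) and interferon genes (0.17) differed. Of these only the A477T glucocorticoid-induced list held with an estimated correlation, at 2 and 4 h (adjusted p = 0.0018 and 0.0059).

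In 5 of 70 groups tested 1 array lay far from the others, where chance gives about 1 in 20 groups. Detected probes numbered 16861 on GRgamma 2 h replicate 1 (others 15352 to 15575) and 17042 on GRalpha 0 h replicate 4 (15619 to 15727). The median signal was 110 on E773R 0 h replicate 3 (200.5 to 211) and 925.75 on A477T 2 h replicate 2 (181.5 to 228). NR3C1 was at 4.88 on A477T 4 h replicate 2 (5.75 to 5.85).

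A first pattern was a set of 49 genes, ATP4A among them, that rose at 4 h in A477T and were not called in GRalpha, with a median response of 1.71 in A477T and 0.06 in GRalpha. Slide differences as the whole cause were argued against by 45 genes still called with slide as a fixed block. A lower 0 h level in A477T was argued against by a median 0 h difference of -0.04 (quartiles -0.24 to 0.13, 1 gene called lower). On the 24 h arrays 98% of these genes were higher in A477T than in GRalpha (all genes 49.2%, median of the set 2.09). A response gained with the allele is thus a candidate explanation, as a hypothesis, and no test here sets the allele apart from the cell population that carries it.

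A second pattern was the lower 4 h score of E773R over the genes that changed most in GRalpha. The array with the fewest detected probes was argued against as the whole cause, since without its number the mean induced score was 2.07 (repressed 0.99) and the lowest GRalpha score was 3.73. A slower response of these genes that had fully caught up by 24 h was also argued against: the induced score genes then stood at 74.9% of GRalpha (3.05 ± 0.18 against 4.07 ± 0.24, SD, n = 4, exact p = 0.0286). At 4 h the induced score had stood at 52.3% of GRalpha, so a response that was slower in part stayed open. A difference between the cell populations stayed open, as did the altered activation domain, and no test here sets them apart.

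A further pattern was a set of 18 genes that differed from GRalpha at 0 h in the same direction in at least 3 variants, 9 higher and 9 lower (independent lists would share 0.0072 and 0.0079). Against the shared GRalpha arrays, 20 simulations of unchanged groups gave 0 such genes. With no gene changed and noise independent between genes and arrays, few calls are likely, so this tests neither the shared arrays nor slide. Splitting the real GRalpha 0 h arrays gave 7 to 9 such genes. A chance deviation of the GRalpha 0 h arrays was argued against by a median signed difference of 1.5 on the separate 2 h arrays (1.32 at 0 h, 1.2 at 4 h and 0.86 at 24 h), and slide differences by 17 genes still called with slide as a fixed block. At 2, 4 and 24 h 83.3% kept the 0 h direction. Differences between the cell populations are a candidate explanation, as a hypothesis, and an effect of the alleles without hormone was not tested apart from them.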

How the results depend on the processing

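The fit without the array with the fewest detected probes, array weights, and the alternatives of the genes shared by all 5 alleles were chosen only after the results were seen, and the cause of a change was not tested except where stated. No filter, a stricter filter, the mean of probes and a replicate block kept all 32 counts of genes within 1.5 times. Replicate numbers paired the arrays weakly. Same-numbered arrays of an allele had a median correlation of deviations of 0.0654 (-0.489 to 0.702, 53 of 120 pairs over 0.1), against -0.0371 for other numbers (130 of 360 pairs). Replicate number explained 15.9, 0.991, 3.19 and 32.6% of the first 4 components of the deviations. The replicate block gave 263 genes in GRalpha at 2 h (224 without it), moved the 15 genes lower in all 5 alleles to 25 and ended the bone matrix list at 2 h (adjusted p = 0.052).

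With the series matrix values the responses at 2, 4 and 24 h gave 489, 1350 and 3945 genes in GRalpha, 557, 1183 and 4054 in GRgamma, 461, 906 and 2230 in A477T, 547, 1000 and 3602 in 30iiB, and 119, 365 and 1832 in E773R. Differences from GRalpha gave 81 and 463 in GRgamma at 4 and 24 h, 1128 in A477T at 24 h, 10 and 101 in 30iiB at 4 and 24 h, and 28, 116 and 572 in E773R. The 0 h counts were 229, 759, 903 and 438 in GRgamma, A477T, 30iiB and E773R, and 2717 genes changed between 4 and 24 h. Higher and lower genes then numbered 239 and 250 in GRalpha at 2 h (164 and 60 from the signals), 329 and 228 in GRgamma at 2 h (166 and 44), 661 and 522 at 4 h (372 and 176), 183 and 278 in A477T at 2 h (120 and 115), 81 and 38 in E773R at 2 h (42 and 3), 186 and 179 at 4 h (92 and 46), and 429 and 474 in 30iiB at 0 h (128 and 70). Differences gave 9 and 5 in GRgamma at 2 h (6 and 8) and 57 and 44 in 30iiB at 24 h (20 and 28).

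Fits to the compared groups alone, with fewer arrays behind the spread, gave 64 genes in GRalpha at 2 h, 70 and 275 in GRgamma at 2 and 4 h, 463 in A477T and 95 in 30iiB at 2 h, and 18 and 21 in E773R at 2 and 4 h. Differences gave 4 and 19 in GRgamma at 2 and 4 h, 2 and 27 in 30iiB at 4 and 24 h, and 6 and 31 in E773R at 2 and 4 h, the 0 h counts were 13, 53 and 17 in GRgamma, 30iiB and E773R, and the 4 to 24 h count was 2169. Scaling to the same median gave 131, 301 and 1456 in GRgamma, 133 and 273 in A477T at 2 and 4 h, 193 in 30iiB at 2 h, and 25, 44 and 399 in E773R, with differences of 29 in GRgamma and 93 in A477T at 4 h and 3 and 13 in 30iiB at 4 and 24 h. The median of all genes then lay 0.11 or further from 0 in 13 contrasts: responses GRgamma 2 h (0.12), A477T 2 and 4 h (-0.11, -0.13) and 30iiB 2 and 4 h (-0.16, -0.16), differences GRgamma 2 h (0.18), A477T 2 h (-0.12), 30iiB (-0.19, -0.14, -0.11) and E773R 2 and 4 h (0.13, -0.11), and 0 h GRgamma (-0.2). Array weights, between 0.129 and 11.4, gave 1283 and 3343 in GRgamma at 4 and 24 h, 1405, 973 and 2538 in A477T, 492 and 903 in 30iiB and 108 and 349 in E773R at 2 and 4 h. Differences gave 84 and 367 in GRgamma at 4 and 24 h, 91, 372 and 1152 in A477T, 17 and 73 in 30iiB at 4 and 24 h and 119 in E773R at 4 h, with 628 in A477T and 353 in 30iiB at 0 h and 3435 between 4 and 24 h.

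Slide as a fixed block gave 318 in GRgamma at 2 h, 1118 in E773R at 24 h, 340 for the E773R difference at 24 h, and 100 and 154 in GRgamma and E773R at 0 h. As a random block (correlation 0.256) it gave 76 and 343 for the 30iiB and E773R differences at 24 h, and 100, 303 and 137 in GRgamma, 30iiB and E773R at 0 h. Cyclic loess gave differences of 23 in GRgamma at 2 h, 12 in 30iiB at 4 h and 40 in E773R at 2 h, and no background correction 3 and 11 in 30iiB at 2 and 4 h. Without the array with the fewest detected probes E773R called 83 at 4 h. Genes higher and lower in all 5 alleles at 4 h numbered 19 and 4 with the same median, 86 and 70 with the series matrix, 15 and 0 with limma on the compared groups alone, and 75 and 61 with array weights, and the lower ones 29 with slide as a random block and 7 without the array with the fewest detected probes.

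Leaving out single arrays moved 23 of 352 counts by over 1.5 times. Ranges follow with the arrays left out for the lowest and the highest count in brackets. The E773R response at 4 h ranged from 83 to 182 (E773R 4 h replicates 2 and 1). The GRgamma difference at 2 h ranged from 9 to 14 (GRgamma 0 h replicates 2 and 4). The 30iiB difference ranged from 0 to 1 at 2 h (30iiB 0 h replicates 2 and 4). At 4 h it ranged from 3 to 10 (30iiB 0 h replicate 2 and GRalpha 0 h replicate 1). At 24 h it ranged from 30 to 47 (GRalpha 0 h replicates 4 and 1). The E773R difference at 2 h ranged from 11 to 26 (lowest without GRalpha 2 h replicate 1, highest without replicate 4). At 0 h GRgamma ranged from 36 to 70 (lowest without GRgamma 0 h replicate 1, highest without replicate 4). A477T then ranged from 191 to 411 and 30iiB from 125 to 281 (both lowest without GRalpha 0 h replicate 4, highest without replicate 1). E773R ranged from 42 to 82 (lowest without E773R 0 h replicate 3, highest without GRalpha 0 h replicate 1).

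Score differences kept their side of the threshold except the A477T repressed score against the mean of the 0 h arrays (-0.47, now past it). Leaving out single numbers, which allows no test under 0.05, gave induced scores of -1.37 to -1.11 for GRgamma, and repressed scores of -0.35 to 0.01 for GRgamma and -0.56 to -0.16 for A477T. Of 66 GRalpha list shifts 12 were lost with an estimated correlation: metallothioneins at 2 and 4 h (adjusted p = 0.18 and 0.21), cell cycle inhibitors (0.38), bone matrix (0.2) and transcription factors (0.07) at 2 h, inflammatory mediators at 4 and 24 h (0.56 and 0.15), TGF-beta and YAP targets at 4 h (0.052), immediate early genes at 4 and 24 h (0.48 and 0.42), and S phase and interferon genes at 24 h (0.15 and 0.26). Cell cycle inhibitors at 2 h were also lost with cyclic loess (0.054), the series matrix (0.21) and slide as a fixed block (0.27), bone matrix without background correction (0.055), with the series matrix (0.098) and slide (0.11), and inflammatory mediators at 4 h without background correction (0.054), with cyclic loess (0.076), the series matrix (0.051) and slide (0.053). Slide as a fixed block brought mitosis at 2 h (0.019) and metallothioneins at 24 h (0.041) past the threshold, and the series matrix TGF-beta and YAP targets at 2 h (0.032). In 148 of 152 called list shifts over all contrasts the highest of the 6 adjusted p-values came with the estimated correlation, and 131 kept the call with slide as a fixed block. Among 1104 values of named genes 1 reversed, KCNMA1 in A477T at 24 h (-0.93, and 0.01 as the mean of probes). Slide as a fixed block ended 30 calls and added 15, the same median ended 216 and added 2, fits to the compared groups ended 189 and added 3, and leaving out single arrays ended 972 of 10712 and added 24. Bounds were given only for genes detected on no array of a group.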

Other observations

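The 18 genes that differed from GRalpha at 0 h in at least 3 variants were chosen after their values were seen. The 9 higher ones were ACTA2, ALDH1L1, ASTN1, FCGRT, H4C3, LHX2, MAGEA10, RGS4 and TGM2, and the 9 lower ones C1QTNF1, DACT1, F13A1, FAM20C, KANK4, NFIB, PTP4A3, SRSF12 and TNFRSF11B. ALDH1L1, a folate enzyme gene, was at 2.61 in A477T, 3.06 in 30iiB and 2.46 in E773R, and the smooth muscle actin gene ACTA2 at 1.74, 1.5 and 1.84. TNFRSF11B, which was also lower in GRalpha at 24 h than at 0 h, was at -1.7 in GRgamma, -1.26 in A477T and -1.71 in E773R.

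Of the immediate early genes 1 of 15 rose in E773R at 2 h, 5 adjusted over the list alone, with a median of 0.6 (camera adjusted p = 5.2e-08, 7.7e-11 with slide as a fixed block, and adjusted p = 0.15 with an estimated correlation), and the difference from GRalpha had a median of 0.8 on a 0 h level of -0.37 (adjusted p = 1.1e-05, and adjusted p = 0.29 with an estimated correlation). At 4 h the E773R difference had a median of 0.67 (adjusted p = 0.0013, and adjusted p = 0.48 with an estimated correlation). In 30iiB at 4 h 7 of 15 fell, 10 adjusted over the list alone, with a median of -1.19 (adjusted p = 1.8e-10, and adjusted p = 0.064 with an estimated correlation). The 30iiB difference from GRalpha then had a median of -0.43 with 0 members called by limma (adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). At 2 h the differences had medians of -0.49 in 30iiB and -0.48 in A477T, and at 24 h 0.79 in E773R (adjusted p = 8.9e-05, 0.021 and 0.0034, and adjusted p = 0.36, 0.65 and 0.56 with an estimated correlation). The list was also called lower in A477T at 2, 4 and 24 h (medians -0.59, -0.82 and -1.29, adjusted p = 0.0063, 6.1e-05 and 1.7e-06), in 30iiB at 2 and 24 h (-0.64 and -1.17, adjusted p = 9.8e-05 each) and in GRgamma at 4 and 24 h (-0.44 and -1.23, adjusted p = 0.04 and 0.00025). None of these 7 held with an estimated correlation (adjusted p = 0.54, 0.33, 0.21, 0.34, 0.34, 0.66 and 0.38). PER1, not called in GRalpha, rose at least 1.94-fold at 2 h and 1.96-fold at 4 h in E773R and by 1.05 at 4 h in GRgamma, but the PER1 differences from GRalpha were not called (0.76 and 1.13 in E773R, adjusted p = 1 and 0.61). PER1 was not detected on the E773R 0 h arrays. Mitosis genes fell in 7 of 27 cases in GRgamma at 24 h, 8 adjusted over the list alone (adjusted p = 0.0062, and adjusted p = 0.58 with an estimated correlation).

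Deviations of the arrays from their group means had a leading component with 26.8% of their variance, of which slide explained 64.1%, and a next one with 16.9%, of which slide explained 36.1%. Arrays of different groups on a shared slide had a median correlation of deviations of 0.359, against -0.0449 on different slides. The split of the GRalpha 0 and 2 h arrays that called 2700 genes set 0 h replicates 2 and 4 and 2 h replicates 1 and 4 (component 2 scores -19.6, -40.6, -35.8 and -43.2) against 0 h replicates 1 and 3 and 2 h replicates 2 and 3 (40.7, 19.5, 40.5 and 38.5). Across 12539 genes (99.9%) the loading and the genomic span of the gene had a Spearman correlation of -0.405, where genes are not independent replicates. The median span was 71 kb in the 500 genes highest with GRalpha 2 h replicate 4, 6.87 kb in the 500 lowest and 29 kb over all genes.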
